A study of Mus musculus with 8 samples.

How the data were processed

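RNA from placentas of Peg11/Rtl1 knockout (KO) and wild-type (WT) mice at embryonic day 12.5 was labelled with Cy3 and hybridised to 8 single-colour Agilent mouse arrays, 1 per sample. The labels give 4 KO and 4 WT samples on a C57BL/6J background, with 2 male and 2 female embryos per genotype. They name placenta as the tissue, while the extraction protocol speaks of the whole embryo. The numbers 1 to 4 within each genotype are the columns of the slide, so KO 1 and WT 1 share a column number, and samples of one number also share the labelled embryo sex (1 and 2 male, 3 and 4 female). All arrays lay on 1 slide, KO in row 1 and WT in row 2, so slide row and genotype cannot be told apart. Likewise, males lay in columns 1 and 2 and females in columns 3 and 4, so embryo sex cannot be told apart from the side of the slide. No label says whether the embryos came from separate litters, and p-values therefore measure the spread between these samples, part of which may be technical.

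The scanner output was made with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. The processed signal of each spot is an intensity on a linear scale, spatially detrended and not normalized between arrays, per the file headers, with a substitute value where a spot did not exceed background. The headers place the 60-base probes on mouse assembly mm9. The authors also deposited a value table, which holds linear intensity values with nearly the same distribution on every array. Its column medians lay between 65.0 for KO 3 and 65.4 for KO 1 (65.4 for KO 2, 65.1 for KO 4, 65.2 for WT 1, 65.3 for WT 2, 65.2 for WT 3 and 65.3 for WT 4). Each column followed the order of the same array's processed signals when matched by feature number, so the table holds no ratio whose direction would be open and is not centred per gene. Medians near 65 are too high for log2 intensities, so its scale was read as linear. The step between arrays that gave this distribution is not given in the sources used here, and the table served only as an alternative.

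Each array held 62976 spots, of which 59305 were not controls. Processed signals were converted to log2 and each array's 75th percentile over the non-control spots was subtracted. Between 466 and 999 spots per array that the scanner software marked as non-uniform or population outliers were left out, and no spot was saturated. Spots of one probe were averaged, giving 55681 probes with 36266 gene names. Of these probes, 26582 (47.7%) carried an accession found in the RefSeq gene table of assembly GRCm38.p6 and took its current symbol, and the others kept the name of the array design. Where a gene had several probes, the one with the highest mean over all 8 arrays stood for it, and an alternative took the mean of all probes. A probe was counted as well above background where at least 0.5 of its spots carried that mark. Genes well above background on at least 4 of the 8 arrays, whatever their group, were tested, as was Rtl1. This left 19077 genes, 18670 of them with a value on every array. Signals are on a relative log2 scale, and levels of different probes were not set against each other. For a probe not well above background on any array of a group, the difference is given as a bound. The bright group's mean was set against the mean, over the dim group's arrays, of the higher of the probe's own signal and the lowest signal among probes well above background.

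Share of probes well above background and signal strength set the precision of an array, beyond which the number of arrays limits it. Between 43.9% (KO 1) and 54.0% (KO 3) of non-control spots were well above background. The 75th percentile of the processed signal lay between 1004 (KO 4) and 1239 (KO 3).

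Tests were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over all genes tested and an adjusted p under 0.05 as threshold. The model held genotype and embryo sex as additive terms over all 8 arrays and had 5 residual degrees of freedom. A second model with the 4 combinations of genotype and sex gave the KO effect within each sex and the interaction. Before the data were examined, 24 gene lists were fixed from textbook markers of placental cell types, pathways and gene families, and 23 of them were tested. Lists were tested with camera at its preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the data and with fry. Camera compares a list with all other genes, and fry asks whether a list's genes move, on balance, one way. Sex chromosome genes served only to check the labelled sex.

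The genes named in the text were set by a rule fixed before the data were examined. It takes Rtl1 and the measured members of the Dlk1-Dio3 list, up to 10 genes per direction past the threshold in KO against WT, or otherwise the 5 per direction with the smallest unadjusted p. It further takes up to 4 members per list by the smallest unadjusted p, the genes past the threshold for sex, and the 3 genes with the smallest unadjusted p for the interaction. Predicted genes without a symbol were counted and not named, except where a count of 5 or fewer included them.

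The steps were tested on simulated arrays with the real gene means, spreads and layout, over 18669 genes of which 200 were changed. For KO against WT the test called 20.9% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 89.4% of those changed 4-fold, with 8 false calls among 133. For male against female it called 28.4%, 74.6% and 98.5%. For KO against WT within males it called 2.99%, 31.3% and 84.8%, within females 0%, 26.9% and 83.3%, and for the interaction 0%, 0% and 56.1%. An endothelial list shifted by -0.5 on the log2 scale was recovered by camera with an adjusted p of 1.3e-53, or 0.000713 with an estimated correlation, and 1 of the 22 other lists was called, which shares members with it. Genes were drawn independently there, while the data gave estimated correlations of 0.0657 for endothelium and 0.725 for yolk sac. The shift was also larger than the observed endothelial median (-0.19). The simulation therefore says nothing on how correlation between genes affects the list calls.

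The alternatives were normexp background correction on the mean and background signals (offset 50), quantile or median scaling, no filter on dim probes or a filter requiring all 8 arrays, the mean of a gene's probes, eBayes with trend and robust settings, array weights, the authors' deposited values, models without sex, with the slide column as a block or with 4 group means, a looser threshold of 0.1 or an added 2-fold limit, and leaving out each array in turn. Alternatives without KO 2 and KO 3, at the preset and at an estimated correlation, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.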

Results

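Gene expression was measured in 8 mouse placentas at embryonic day 12.5, 4 from Peg11/Rtl1 KO and 4 from WT embryos, each with 2 males and 2 females. Rtl1 (also Peg11) is a paternally expressed imprinted gene derived from a retrotransposon, in the Dlk1-Dio3 domain of chromosome 12. The study set out to find genes involved in keeping the endothelium of the fetal capillaries, the vessels of the placental labyrinth in which fetal blood runs. Between 43.9% and 54.0% of spots per array were well above background. All values are log2 signals relative to the array's 75th percentile, and differences are KO minus WT unless stated.

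The Rtl1 probe (mm9 chromosome 12, 110828379 to 110828438) gave lower signals on every KO array than on any WT array. The KO arrays read -5.39, -5.95, -5.96 and -5.64, and the WT arrays -2.74, -4.48, -4.51 and -4.42. The group means were -5.74 ± 0.27 (SD, n = 4) in KO and -4.04 ± 0.87 (SD, n = 4) in WT. The probe was well above background on 0 KO arrays and on 1 WT array, WT 1, so its readings are mostly background. The bound set against background was 0.898-fold (WT over KO), under 1, so no size of the difference can be given; the adjusted p over all genes was 0.253. The labels do not give the extent of the deletion, so whether this probe lies within it is not known, and the direction of the signal goes with the labels without settling them.

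The other listed genes of the Dlk1-Dio3 domain differed by -0.33 to 0.43 between genotypes. Mirg, a maternally expressed non-coding RNA that hosts microRNAs, was lower on all KO arrays (-0.33, SE 0.09, adjusted p = 0.264). Meg3, the long non-coding RNA of the maternal chromosome, differed by -0.17 (SE 0.12), and the paternally expressed Dlk1 and Dio3 by 0.13 (SE 0.31) and -0.09 (SE 0.09). Among neighbours, Begain differed by 0.43, Dio3os by 0.39, Wdr25 by 0.32, Slc25a47 by 0.21, Ppp2r5c by 0.14, Dync1h1 and Slc25a29 by 0.10 each, Degs2 by 0.08, Wars by 0.07, Yy1 by -0.08 and Evl by -0.01. Dlk1, Slc25a47, Ppp2r5c, Dync1h1, Slc25a29, Degs2, Yy1 and Evl turned direction under at least 1 alternative. Of the 16 measured members, 10 were higher and 6 lower, 0 passed over all genes, and Rtl1 was the 1 member that passed when adjusted over the list alone (0.0411). The list did not stand out from other genes by camera (adjusted p = 0.591), with a median of 0.09, a mean of -0.03 and a test direction that pointed down.

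**Figure D1:**
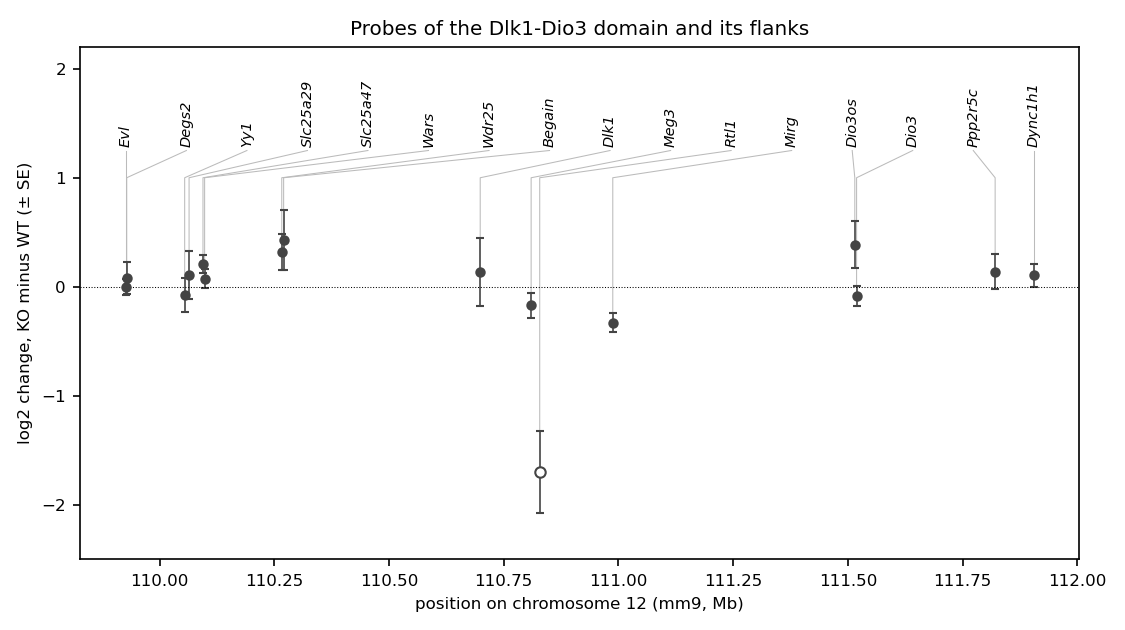
Difference between KO and WT (log2, ± SE of the limma fit, 4 arrays per group) for the probes of the Dlk1-Dio3 domain and its flanks, drawn at their mm9 position on chromosome 12 in megabases. The open point is Rtl1, whose probe was not well above background on any KO array, so its height gives no size. The other genes lie between -0.33 and 0.43.

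The single gene with the smallest p between genotypes was Lyve1, a hyaluronan receptor found on lymphatic endothelium and on some embryonic blood vessels and macrophages. Its signal was -2.26 ± 0.27 (SD, n = 4) in KO and -0.31 ± 0.27 (SD, n = 4) in WT, a difference of -1.95 (SE 0.17) or 3.86-fold, lower on all 4 KO arrays. Tmem100, an endothelial membrane protein downstream of the BMP9 and ALK1 pathway, was lower by a similar pattern, at 0.32 ± 0.23 (SD, n = 4) against 1.42 ± 0.28 (SD, n = 4), a 2.14-fold difference (SE 0.13 on the log2 scale). Slc12a5, a neuronal potassium-chloride cotransporter, differed by -0.99 (SE 0.12), Mapt, which encodes the microtubule protein tau, by -0.66 (SE 0.08), and Rasa1, a Ras GTPase-activating protein needed for vascular development, by -0.54 (SE 0.08), each lower on all 4 KO arrays. Higher in KO were Gnai2, a G protein subunit (0.99, SE 0.13), Kcnd1, a potassium channel (0.81, SE 0.09), Plin4, a lipid droplet protein (0.75, SE 0.11), Tex15, a germ cell gene (0.70, SE 0.10), and Sprtn, a protease that repairs DNA-protein crosslinks (0.67, SE 0.08). Plin4, Tex15 and Sprtn lay above WT on all 4 KO arrays, while Kcnd1 and Gnai2 lacked a value on 1 array each.

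Some of these sizes rest on the processing: with normexp Slc12a5 was at -0.66, Mapt at -0.43 and Sprtn at 0.31, and with the mean of all probes Slc12a5 was at -0.48, Kcnd1 at 0.19 and Tex15 at 0.34. None of these genes passed the adjusted threshold. Lyve1 had the smallest adjusted p at 0.126, Slc12a5, Tmem100, Mapt and Sprtn had 0.188, and the other 5 had 0.194. Of 19077 genes, 0 had an adjusted p under 0.05 by limma, and 2477 had an unadjusted p under 0.05, where 954 would be reached by chance, 1830 of them higher and 647 lower in KO. All 4 KO arrays lay above all 4 WT arrays for 930 genes and below for 365, together 6.94% of the 18670 genes with full values, against 2.86% by chance. KO 2 and KO 3 stood apart from the other arrays on the first principal component (63.5 and 39.6, others -27.4 to -0.12), which held 42.7% of the variance. Without these arrays 0 genes passed and 1815 had an unadjusted p under 0.05, 1079 of them higher, and without KO 3 alone the count was 1609.

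**Figure D2:**
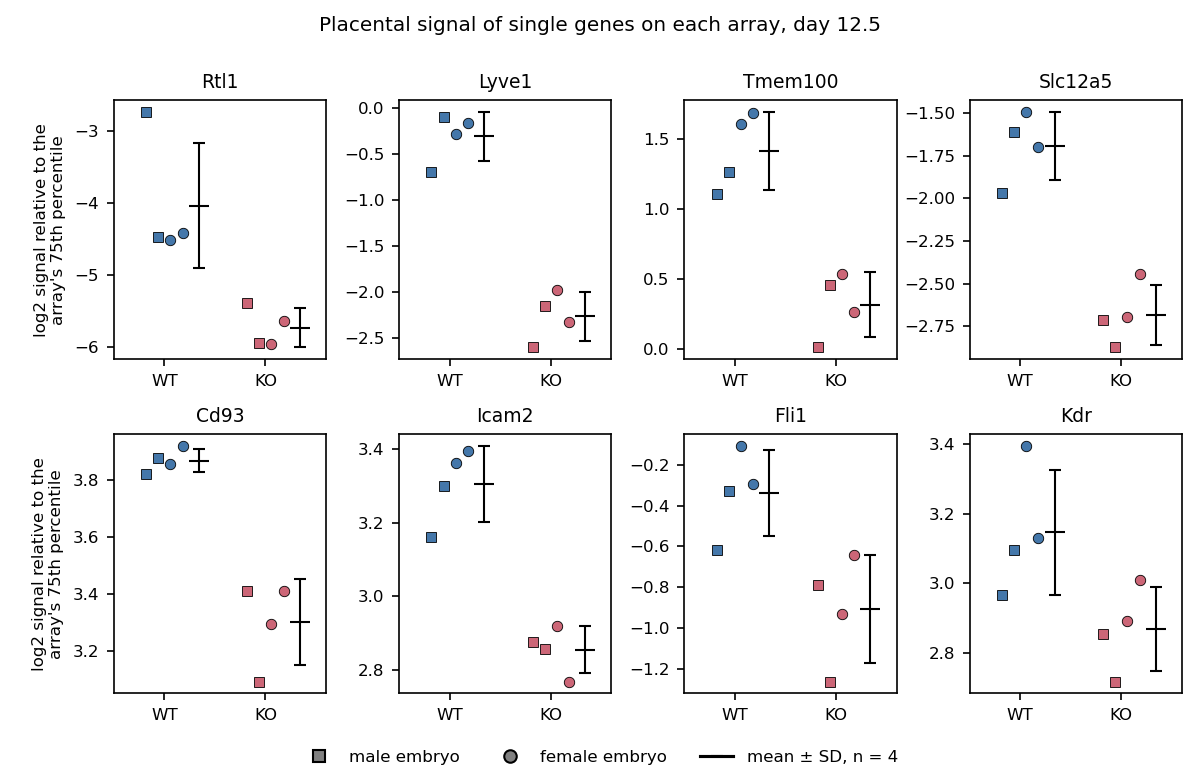
Log2 signal relative to the array's 75th percentile for Rtl1, Lyve1, Tmem100, Slc12a5 and the endothelial genes Cd93, Icam2, Fli1 and Kdr on each of the 8 arrays, squares for male and circles for female embryos, with mean ± SD of 4 arrays. KO and WT arrays do not overlap for any of the genes drawn except Kdr.

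Endothelial genes fell in KO as a group by camera at the preset correlation (adjusted p = 6.4e-08), but not with an estimated correlation (adjusted p = 0.174) or by fry (0.0876). Of 41 measured members, 32 were lower and 9 higher, with a median of -0.19. The list's mean was lower on each KO array (-0.25 to -0.05) than on any WT array (0.03 to 0.18), as was that of the vessel growth genes given below. Lyve1 led the list, followed by Cd93, a receptor of endothelial and myeloid cells (-0.57, SE 0.10), Icam2, an endothelial adhesion molecule (-0.45, SE 0.08), and Fli1, an ETS transcription factor of endothelial and blood cells (-0.57, SE 0.14; -0.38 without KO 2 and KO 3). Each of these 4 was lower on all KO arrays. Kdr, the main VEGF receptor of endothelium, differed by -0.28 (SE 0.09). Not all members went this way: Cd34 (0.80) and Vwf (0.33), named here after their values were seen, were higher on all KO arrays, and Tie1 (-0.03) and Emcn (0.05), chosen in the same way, lay near 0.

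The call of the endothelial list thus rests on the preset correlation. Of its members, 0 passed over all genes and 4 passed when adjusted over the list alone, Lyve1, Cd93, Icam2 and Fli1. The median was -0.10 in males and -0.22 in females. KO 2 was the lowest array at -0.25, with 2 members, Cdh5 and Aplnr, among the probes lower by over 1 on both KO 2 and KO 3, and without KO 2 and KO 3 the list median was -0.16 and the adjusted p 2.5e-06, or 0.818 with an estimated correlation as well; over all alternatives it ran from 2.9e-09 to 0.818.

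Other groups of the vessel bed were not called, which does not show that they differed from endothelium. Ligands and receptors of vessel growth had 16 of 32 members lower and a median of -0.01 (adjusted p = 0.347). Their list mean was nevertheless lower on each KO array (-0.08 to -0.04) than on any WT array (0.001 to 0.12). By chance 2.86% of lists would separate in either direction. Among these genes Pgf, a placental VEGF relative, differed by 0.34, Tgfb1 by 0.31 and the Notch target Hey1 by -0.29. Stroma and pericytes had 12 of 22 members lower and a median of -0.04 (adjusted p = 0.0647), with Gucy1a1, a subunit of the nitric oxide receptor, at -0.42, Tagln at -0.27 and Myh11, both smooth muscle genes, at -0.57; at the preset correlation this list was called, pointing down, without KO 2 (0.0118), without WT 1 (0.0110), with array weights (0.0493) and without sex in the model (0.0393), against an adjusted p of 0.728 with an estimated correlation on all arrays. Basement membrane and matrix genes had 16 of 25 members higher and a median of 0.14 (adjusted p = 0.591), with Fn1 at 0.36, Sparc at 0.35 (-0.34 as the mean of its probes), Mmp14 at 0.36 and Nid1 at 0.26. In these 3 lists 0 members passed over all genes and 0 when adjusted over the list alone.

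**Figure D3:**
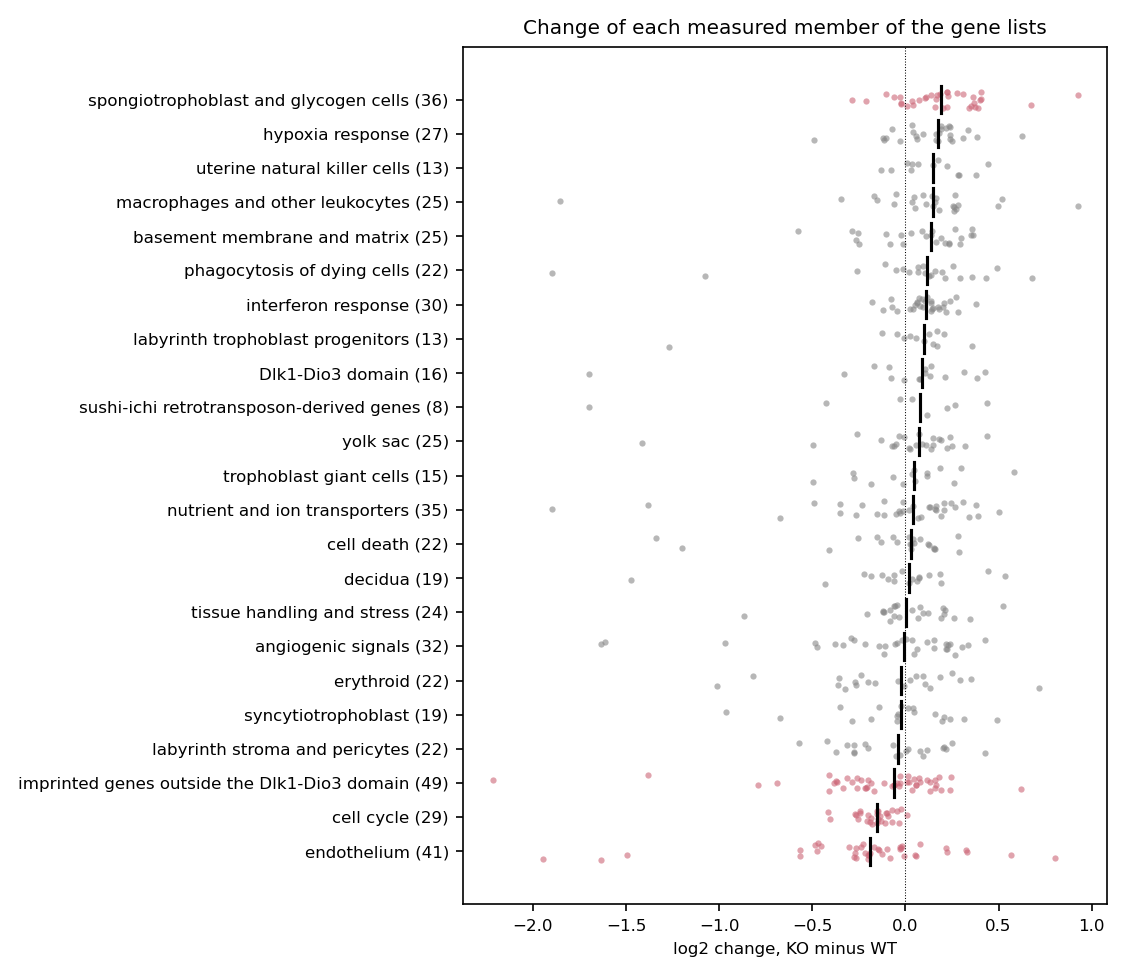
Difference between KO and WT (log2) of each measured member, as a dot, for the 23 gene lists tested, with the number of measured members in brackets and the median as a bar; lists with an adjusted p under 0.05 by camera at the preset correlation are red. The medians run from -0.19 for endothelium to 0.19 for spongiotrophoblast and glycogen cells.

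Almost every cell cycle gene had a lower mean in KO, by small amounts, though not every KO array was lower. Of 29 members, 28 were lower, with a median of -0.15, and 5 had an unadjusted p under 0.05. Pcna, the sliding clamp of DNA replication, differed by -0.26 (SE 0.07), the mitotic cyclins Ccnb2 and Ccnb1 by -0.27 (SE 0.08) and -0.40 (SE 0.16), and Cdc6, a licensing factor of replication origins, by -0.42 (SE 0.15). The list fell by camera (adjusted p = 1.4e-08), with an adjusted p of 0.763 with an estimated correlation and 0.305 by fry. Of its members 0 passed over all genes and 0 when adjusted over the list alone. WT 1 had the highest list mean at 0.24 against 0.01 to 0.05 on the other WT arrays. KO 1 (-0.16) and KO 4 (-0.14) had the lowest, KO 2 lay at -0.04, and KO 3 (0.01) lay among the other WT arrays. Without WT 1 the median kept 0.612 of its size. Members moved together across arrays (estimated correlation 0.509), so their count does not stand for as many separate observations.

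Imprinted genes outside the Dlk1-Dio3 domain had a median of -0.06 over 49 members, 29 lower and 20 higher. Magel2 (-0.37, SE 0.09), Kcnq1, a potassium channel gene (-0.41, SE 0.12), Mest, a paternally expressed hydrolase gene (-0.31, SE 0.09), and the non-coding Peg13 (-0.26, SE 0.08) were lower on all KO arrays. By camera the list fell (adjusted p = 0.00326), with an adjusted p of 0.174 with an estimated correlation. No member passed over all genes or when adjusted over the list alone, a count of 0 by limma beside 7 members at an unadjusted p under 0.05. The lowest means were those of KO 2 (-0.31) and KO 3 (-0.14), where the probes of 3 members, Gatm, Grb10 and Slc22a3, were lower by over 1 on both, while KO 1 (0.09) and KO 4 (0.04) lay close to the WT arrays (0.05 to 0.11). Without KO 2 and KO 3 the adjusted p was 0.409, and with normexp background correction 0.0955; over all alternatives it ran from 0.000795 to 0.818.

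Trophoblast genes of the junctional zone, the layer between the labyrinth and the decidua, mostly read higher in KO. Of 36 members of the spongiotrophoblast and glycogen cell list, 29 were higher, with a median of 0.19. Aldh1a3, a retinaldehyde dehydrogenase (0.67, SE 0.16), Psg21, a pregnancy-specific glycoprotein (0.35, SE 0.09), and Pcdh12, a protocadherin of glycogen cells (0.40, SE 0.12), were higher on all KO arrays, and Car2, a carbonic anhydrase, differed by 0.39 (SE 0.12). The list rose by camera (adjusted p = 0.00889), with an adjusted p of 0.812 with an estimated correlation. Of its members 0 passed over all genes, 0 when adjusted over the list alone, and 10 had an unadjusted p under 0.05, all higher. The adjusted p was 0.0619 without KO 1, 0.206 without KO 4 and 0.190 without WT 4, and it was 0.134 with normexp, 0.0792 with quantile scaling and 0.0979 with the authors' values.

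**Figure D4:**
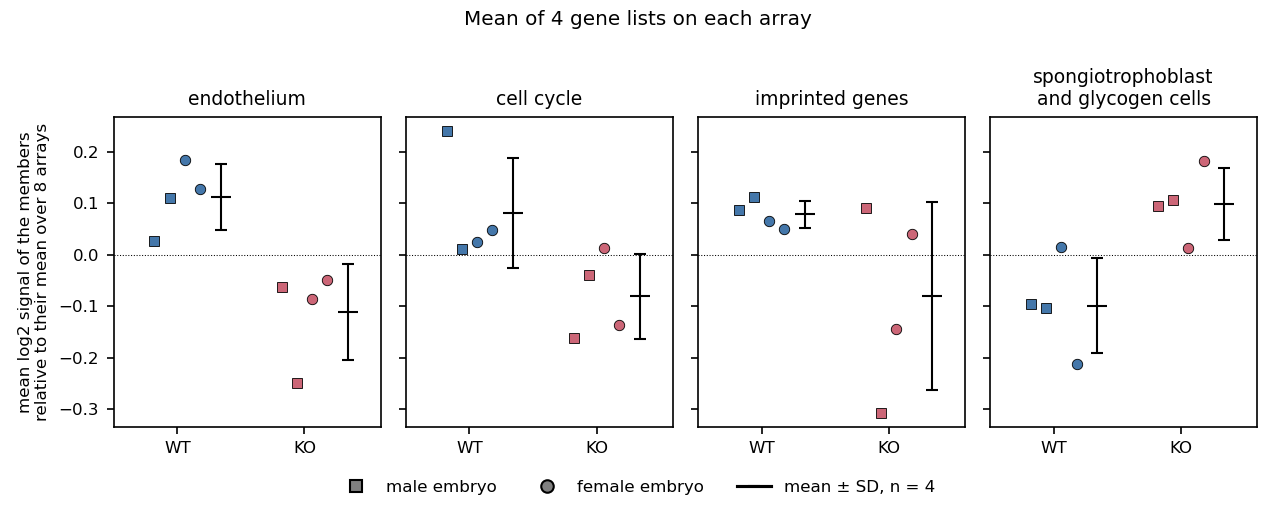
Mean log2 signal of the members of 4 gene lists on each array, relative to each member's mean over the 8 arrays, squares for male and circles for female embryos, with mean ± SD of 4 arrays. KO and WT arrays do not overlap for endothelium, while KO 2 and KO 3 are the lowest arrays for imprinted genes at -0.31 and -0.14.

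The remaining trophoblast lists were not called. Syncytiotrophoblast, the fused trophoblast layers of the labyrinth, had 10 of 19 members lower and a median of -0.03 (adjusted p = 0.591). The fusion gene Syna was at 0.49, the lactate transporter Slc16a1 at -0.67 (well above background on only 2 KO arrays) and the transferrin receptor Tfrc at -0.35. Vgll1, a cofactor of TEAD transcription factors, was at -0.96 (SE 0.17) with values on 2 WT arrays only, and was the 1 member that passed when adjusted over the list alone (0.0375). Its direction turned with the mean of its probes in place of the brightest (0.32). Labyrinth trophoblast progenitors had a median of 0.10 (adjusted p = 0.693), with Fgfr2 at 0.36 and Esrrb at 0.21. Epcam, a marker of these progenitors, was at -1.27 (SE 0.63), and it was low on KO 2 (-1.18) and KO 3 (-0.88) against 0.95 to 1.66 on the other arrays; its probe is one of 688 that were lower by over 1 on both KO 2 and KO 3 than on the other arrays. Giant cells had a median of 0.04 (adjusted p = 0.898), with Hand1 at 0.26, the cathepsins Cts3 at 0.30 and Ctsq at 0.18, and the proliferin Prl2c5 at -0.50 (0.12 with normexp). Progenitors and giant cells each had 0 members past the threshold when adjusted over the list alone, as over all genes.

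Maternal and blood cell markers gave no call with all arrays. Decidua had a median of 0.02 (adjusted p = 0.591), with Wnt4 at 0.53, Greb1 at 0.44 and Bmp2 at -0.43. Uterine natural killer cells had 11 of 13 members higher and a median of 0.15 (adjusted p = 0.591), with the interleukin receptor chain Il2rb at 0.38 and perforin, Prf1, at 0.45. Macrophages and other leukocytes had a median of 0.15 (adjusted p = 0.564), with Itgam at 0.52, Cd68 at 0.49 and Csf1r at 0.26. Erythroid genes had a median of -0.02 (adjusted p = 0.564; 0.0132 without WT 3, pointing down; adjusted p of 0.853 with an estimated correlation on all arrays). Gata1, the transcription factor of red cell precursors, was higher on all KO arrays at 0.72 (SE 0.12, adjusted p = 0.194) and was the 1 member that passed when adjusted over the list alone (0.00899). Epb42, a membrane protein of red cells, was at -0.82 and Tmcc2 at -1.01. Epb42 was well above background on only 2 KO arrays and Tmcc2 on only 1, so neither size is firm. In the decidua, natural killer and leukocyte lists 0 members passed on either adjustment.

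Among pathways, genes for the uptake of dying cells had 16 of 22 members higher and a median of 0.12 (adjusted p = 0.538; 0.0876 by fry), with the receptor Axl at 0.49, Lrp1 at 0.43 and Stab2 at 0.29. Apoptosis genes had a median of 0.03 (adjusted p = 0.591), with Cycs, cytochrome c, at -0.41 and Diablo at 0.29 (-0.13 as the mean of its probes). Hypoxia genes had 21 of 27 members higher and a median of 0.17 (adjusted p = 0.347), with P4ha2 at 0.39 and the glucose transporter Slc2a1 at -0.49. Nutrient and ion transporters had a median of 0.04 (adjusted p = 0.591), with the amino acid transporter Slc7a8 at 0.27. Interferon response genes had 25 of 30 members higher and a median of 0.11 (adjusted p = 0.347), with Oasl2 at 0.38 and Irf7 at 0.22. Immediate early and stress genes were split 12 to 12 (adjusted p = 0.730), with Gadd45b at 0.26. In these 6 lists 0 members passed on either adjustment. The family of Rtl1, genes derived from sushi-ichi retrotransposons, had a median of 0.08 over 8 members (adjusted p = 0.898). In it Rtl8c, at 0.44 (SE 0.09, lowest 0.18 over the alternatives), passed with Rtl1 when adjusted over the list alone (0.0103 each).

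Median, mean and test direction differed in sign for several lists without a call. The median difference over all genes was itself 0.06, and 0.05 with quantile scaling, 0.09 with median scaling and 0.05 with the authors' values. Camera sets a list against all other genes, so a list with a median just above 0 can point down. Counts of members higher in KO and list medians above 0 are likewise to be read against this shift. The median was above 0 and both mean and test pointed down for decidua, apoptosis and transporters. The test alone pointed down for giant cells, yolk sac and the stress genes, and the mean alone was below 0 for labyrinth progenitors (-0.01) and the Rtl1 family (-0.13). Of the 23 lists, 4 were called by camera at the preset correlation, 0 with an estimated correlation and 0 by fry, which leaves the group results dependent on how strongly genes of a list are taken to vary together.

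Markers of the visceral yolk sac, a neighbouring fetal membrane, varied widely between arrays of both genotypes (median 0.07 over 25 members, adjusted p = 0.591, 0 members past either adjustment). The list's mean was 1.80 on KO 2, 1.14 on WT 4, 0.26 on WT 1, 0.12 on KO 1, -0.11 on WT 3, -0.25 on KO 3, -1.40 on WT 2 and -1.62 on KO 4. The list's median difference was 1.43 in males and -1.44 in females, so the value near 0 joins opposite ones; the difference between the sexes was not tested for the list. Cldn2 differed by 0.44 (SE 0.33), Apob by -1.41 (SE 1.06; 0.06 as the mean of its probes) and Gata4 by 0.25 (SE 0.22). Without KO 2 and KO 3 the list had an adjusted p of 0.0293 by camera, pointing down, and an adjusted p of 0.998 with an estimated correlation. It was 0.00639 without KO 2 alone and 0.00934 without WT 2, also pointing down.

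Embryo sex was clear from the sex-linked genes and went with every label. The Y-linked RNA helicase gene Ddx3y was at least 30.2-fold higher in males (0.85 ± 0.39 against -5.96 ± 0.61, SD, n = 4; adjusted p = 0.00111) and the Y-linked translation factor gene Eif2s3y at least 28.0-fold (males -0.70, 0.51, 1.81 and 1.34, females -6.98 to -5.68; adjusted p = 0.00640). Neither was well above background on any female array. Xist, the RNA that silences an X chromosome in females, was lower in males by -3.07 (SE 0.22, adjusted p = 0.0365), and a separate array entry for XIST by -3.22 (SE 0.30, adjusted p = 0.0389). An entry without a gene symbol on chromosome 9 (mm9, 13411366 to 13411425), named because the count was small, was higher in males by 1.04 (SE 0.09, adjusted p = 0.0365). Its probe was well above background on 4 male but only 2 female arrays, so this size is not firm. Among the alternatives it passed only with array weights. These 5 entries, 3 higher and 2 lower in males, were all that passed by limma among 19076 genes, beside 2067 at an unadjusted p under 0.05. Apart from the Y-linked and Xist entries, sex cannot be told apart from slide column in these counts, and this holds for the chromosome 9 entry too. Leaving out one array left 3 entries without KO 1, KO 2 or WT 1, 2 without KO 4, and 1, Ddx3y, without KO 3, WT 2, WT 3 or WT 4.

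The KO effect was also compared between the sexes. By limma 0 of 19060 genes passed for the interaction, with 407 at an unadjusted p under 0.05, fewer than the 953 that would be reached by chance. The smallest p belonged to Cd86, a costimulatory molecule of antigen-presenting cells, Homer3, a scaffold protein, and Pdik1l, a kinase. Their KO effects in males minus those in females were 1.64, 1.11 and -1.12, with an adjusted p of 1 each. The value of Pdik1l gives no size, because only 2 WT arrays, both male, were well above background for its probe. Within males 0 genes passed and 1080 had an unadjusted p under 0.05, and within females 0 passed and 1170 had one, against 953 by chance in each. Over all alternatives the counts at an unadjusted p under 0.05 ran from 292 to 1453 for the interaction, 605 to 3726 in males and 741 to 1634 in females. Without KO 4, Atrx passed for the interaction and within females, without WT 3 Ddx59 passed within females, and without WT 2 an entry on chromosome 1 without a gene symbol passed within males, all named after their values were seen. Atrx read -5.91 on KO 3 and Ddx59 -5.89 on WT 4, far below their other arrays. With 2 arrays per sex and genotype, the simulated arrays gave calls for 56.1% of 4-fold interactions and for 0% of 2-fold ones, so a difference between the sexes of that size was not detectable here.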

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

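Chosen only after the result was seen were the tests of yolk sac, of ribosomal RNA, of an even loss of endothelial cells, of less labyrinth and of the number of genes passing in other splits, the counts of splits in which any list did as well and of splits balanced for sex, and the fit without KO 2 and KO 3.

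KO 2 and KO 3 stood apart from the other 6 arrays in 688 of 24178 detected probes that were lower by over 1 (log2) on both, against at most 109 for any other of the 28 pairs of arrays. Only 35 probes were higher by over 1 on both, while another pair had 293, so the pair is set apart by its lowered probes alone. Examples of these are one probe of Ubfd1 (-6.32 and -4.62) and of Gatm (-5.82 and -4.45). The tables argue against spot position (lowered spots lay next to another 1.07 times as often as random spots), GC content (rho 0.0636), blocks of DNA of another strain (0.735 times as many lowered neighbours as shuffled genes) and yolk sac, whose markers deviated by 2.06 on KO 2 but by 0.0116 on KO 3 (SE over members 0.0581, with a wider spread between arrays); their mean was lower on KO 3 (-0.25) than on KO 1 (0.12), WT 1 (0.26), WT 3 (-0.11) and WT 4 (1.14), which did not stand apart. On KO 3 Afp (4.07) and Ttr (0.23) lay below KO 2 (6.58 and 3.18), all 25 measured markers were well above background on at least 4 arrays, and Sox17 is also in the endothelial list. The tables also argue against a change of whole transcripts, since other probes of 242 lowered genes deviated by a median of -0.27 against -1.86 for the lowered probe (ratio 0.147), though the lowered probe was picked as low, while loss of 5' sequence stays open, with the probe nearer the 5' end lower in 76 of 127 pairs (0.598, interval 0.508 to 0.684). A candidate explanation is a share of signal from ribosomal RNA in these probes. Rn18s was lower by -6.34 on KO 2 and -6.65 on KO 3. Over the other 6 arrays the lowered probes followed Rn18s with a median correlation of 0.605 against 0.0673 for other probes. Rn18s is itself one of the lowered probes, however. Any factor that these probes share could give this correlation, so it cannot single out ribosomal RNA.

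The endothelial list was lower in KO by camera at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.174) and with fry (0.0876). The real split alone gave this list a camera p as small (1 of 35; -log10 p 8.26, highest other 7.75), but chance is not excluded: of the 18 splits balanced for sex it is 1, too few for a share under 0.05 (highest other 7.21), and in 12 of 35 splits some list of the 23 had a camera p as small. KO 2 and KO 3 were not the whole of it, since the median without them kept 0.821 of its size (-0.16). Of 41 members, 12 (0.293) lay over 2 standard errors from the list's median, 8 above and 4 below. This cannot decide on an even loss of endothelial cells, because members such as Cd93 and Fli1 are also made by other cells. In addition, 2 members are among the probes lowered on KO 2 and KO 3, and the same share was not taken over all genes. Less labyrinth in the KO samples stays open, because the syncytiotrophoblast median lay above the endothelial one by 0.165 with a standard error of 0.139, and so does slide row, which cannot be told apart from genotype. An effect of the KO on some endothelial genes, Lyve1 among them, remains a hypothesis.

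The cell cycle list was lower in KO in 28 of 29 members (adjusted p = 0.763 with an estimated correlation), and chance could not be excluded, as 3 of 35 splits gave a camera p as small (-log10 p 9.21, highest other 19.1). A single array stays open as a cause: without WT 1 the median kept 0.612 of its size, which is neither under 0.5 nor over 0.8. WT 1 lay at 0.24 on the list mean, far from the other WT arrays (0.01 to 0.05), and KO 3 (0.01) lay among those. An effect of genotype on dividing cells stays open and was not tested.

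For the other results, chance could not be excluded for genes at an unadjusted p under 0.05 (3 of 35; real 2477, highest other 4021), for the imprinted list (4 of 35; -log10 p 3.37, highest other 3.81) or for the spongiotrophoblast list (7 of 35; 2.81, highest other 9.84). For sex the real split alone gave as many (1 of 35, real 5, highest other 2), the smallest share these splits can give. Most of these entries are the Y-linked and Xist ones that check the labels, so the count says little on chance for other genes. The 18 splits balanced for genotype are too few for a share under 0.05, and the split by sex is also the split by side of the slide. The count of genes in KO against WT says nothing on chance, because any split has at least the real 0 (35 of 35; the highest other, 4, was the split by sex). The real split called 4 lists, 20 of 35 splits called as many, and another called 12; structure among the arrays was not told apart from a preset correlation too low for some lists (estimated at up to 0.725).

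Of 270 groups of 4 arrays, 9 held an array far from the other 3, where 13.5 would by chance. Besides the cell cycle list, these were Rtl1 on WT 1 (-2.74, others -4.51 to -4.42), Tex15 on KO 1 (-1.91, others -2.14 to -2.12), Aldh1a3 on KO 3 (3.41, others 3.95 to 4.01), Diablo on WT 4 (2.59, others 2.38 to 2.40), Hoxa9 on WT 1 (-1.82, others -1.94 to -1.92) and Gzmc on KO 2 (5.30, others 4.79 to 4.86). The remaining ones were the tissue handling and stress list on KO 3 (-0.13, others 0.04 to 0.07) and the 75th percentile signal of KO 4 (1004, others 1204 to 1239).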

How the results depend on the processing

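The fits without KO 2 and KO 3 were chosen after the data were seen. For KO against WT 0 genes passed under all 15 other settings and with each array left out, with the slide columns as a block included (2437 at an unadjusted p under 0.05). The fitted value of Rtl1, which gives no size as its probe was not well above background on any KO array, was below 0 throughout (-1.76 to -0.63 over the settings, -1.97 to -1.28 with an array left out, -1.70 with the block). Of 114 results for named genes, 98 kept their direction under the alternatives run for them (at most 18; not the models without sex, with the block or with 4 group means), and 0 newly passed the threshold, while 72 turned or lost over 1.5 times in size under at least 1 of them. The 16 that did not, none past it, were Vgll1, Sparc, Diablo, Lcp1, Hoxa9 and Apob (mean of all probes), Prl2c5 and Slc25a47 (normexp), Slc13a4 (without KO 2), and Dlk1, Dync1h1, Ppp2r5c, Degs2, Yy1, Slc25a29 and Evl (more than 1 setting). The numbers 1 to 4 did not pair the samples evenly: same-number correlations were 0.380, -0.280, 0.117 and 0.0399. Of the same-number pairs, only KO 1 and WT 1 were each other's best match, while KO 3 and WT 4 were so across numbers. A gradient along the columns was present, however. The second principal component (20.2% of the variance) rose with the column number in both rows. It ran from -20.1 (KO 1) to 23.4 (KO 4) and from -25.6 (WT 1) to 42.6 (WT 4). Column and embryo sex cannot be told apart in it.

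The count for sex was 3 with quantile scaling, the mean of all probes or the authors' values, 2 without a filter or without KO 2 and KO 3, 0 with the filter on all 8 arrays, and 1 to 3 with an array left out; the Y-linked genes leave the test under that filter, and leaving arrays out lowers the degrees of freedom, while the cause of the other changes was not tested. With an array left out, 0 to 1 genes passed for the interaction (Atrx without KO 4), in males (an unnamed chromosome 1 entry without WT 2) and in females (Atrx without KO 4, Ddx59 without WT 3); Atrx was at -5.91 on KO 3 and Ddx59 at -5.89 on WT 4, each then the only female array of its group.

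The number of lists called was 4 with the block, 2 with normexp, 0 with an estimated correlation, 0 with fry and 3 to 6 with an array left out. Called there and not with all arrays were stroma and pericytes (without KO 2 or WT 1, with array weights or without sex), yolk sac (without KO 2 or WT 2, or without KO 2 and KO 3), erythroid (without WT 3) and the sex chromosome list (0.0313 without WT 1, where it came to 3 full members). With an estimated correlation and with fry, the adjusted p was 0.174 and 0.0876 for endothelium, 0.763 and 0.305 for cell cycle, 0.174 and 0.193 for imprinted genes, and 0.812 and 0.170 for spongiotrophoblast; both let genes vary together. With an estimated correlation and without KO 2 and KO 3, 0 lists were called and each of these 4 had 0.818. The imprinted list had 0.0955 with normexp and 0.409 without KO 2 and KO 3, and spongiotrophoblast 0.134 with normexp, 0.0792 with quantile scaling and 0.0979 with the authors' values, where the cause was not tested. With an array left out, the ranges were 2.9e-09 to 9.9e-06 for endothelium, 1.3e-11 to 8.1e-05 for cell cycle, 0.00127 to 0.0359 for imprinted genes and 0.000113 to 0.206 for spongiotrophoblast (over the threshold without KO 1, KO 4 or WT 4). With the block they were 9.5e-07, 1.0e-07, 0.00351 and 0.00845. Signal over background limits Rtl1, with 0 KO arrays and 1 WT array well above it.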

Other observations

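The entries between the Meg3 and Mirg probes were looked at only after their values were seen; the test near Rtl1 was planned before its result.

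Of 14 array entries with probes from Meg3 to Mirg on mm9 chromosome 12, Rtl1 included, 13 had a lower mean in KO, 7 had all KO arrays below all WT arrays, and 7 had an unadjusted p under 0.05. The nearest, 6430411K18Rik (110830889 to 110830948), read -3.85 ± 0.30 (SD, n = 4) in KO and -2.75 ± 0.32 (SD, n = 4) in WT, a 2.15-fold difference with an adjusted p of 0.228. Its KO mean lay among the lowest signals well above background on the KO arrays (-4.79 on KO 3 to -3.28 on KO 1), so this size is not firm. The next, 1110006E14Rik (110836685 to 110836744), read 0.98 ± 0.15 against 1.55 ± 0.12 (SD, n = 4 each), a difference of -0.57 (SE 0.10, adjusted p = 0.228). Unnamed entries with probes starting at 110897958 and 110913620 differed by -0.66 (SE 0.18) and -0.56 (SE 0.12), each lower on all KO arrays, and Mirg, at the far end, by -0.33 (SE 0.09). The entry whose probe starts at 110871940 was higher (0.16, SE 0.10), and Meg3 differed by -0.17 (SE 0.12). By limma 0 of the 14 passed over all genes, the entries as a group were not tested, and whether some belong to one transcript is not known.

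Genes along a wider stretch were tested for a hypothesis on strain. DNA of another strain kept around the altered locus could change nearby genes or their probes' binding. Of 198 genes with a probe within 10 Mb of that of Rtl1, 16.7% had an unadjusted p under 0.05 against 12.9% of other genes, 1.29 times as many. The 198 leave out Rtl1 but include the other entries from Meg3 to Mirg given above, so part of this excess is not a separate observation. This lies between the share that such DNA would give (at least 2 times) and that without it (at most 1), so the question stays open.

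Yolk sac markers spread widely and alike over arrays of both genotypes. Afp read 6.58 on KO 2, 5.94 on WT 4 and 0.56 on KO 4, and Alb 2.34, 0.83 and -5.32 on the same arrays. Leukocyte markers had their highest list means on KO 2 (0.45) and WT 1 (0.35).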
